A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

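Total RNA of budding yeast was measured on biotin-labelled Affymetrix arrays that also carry probe sets for genes of another yeast. Both strains are BY4741 derivatives of mating type a, were grown in YPD and were kept at 37 °C for 60 min before RNA was extracted with acid phenol and a column kit, per the labels' protocols. The chromosomal ACS2 gene is deleted in both, per the labels, and a centromeric URA3 plasmid supplies either wild-type ACS2 or the temperature-sensitive allele acs2-Ts1. The titles of both samples carry the abbreviation for wild type, so the groups were taken from the genotype field. Each group is 1 sample.

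The deposited values are probe set intensities on a linear scale, and per the labels and the series' design text the authors corrected 4 arrays for background, took the mean of the 2 arrays of each strain and normalized both means with a lowess curve on controls. RMA is named by the submitters' processing notes. Per the labels, scaling and quantile normalization were avoided because expression shifted globally, and significance was judged against a null set, which was not used here. Which controls the curve was fitted on, the summary step and the software versions are not given in the sources used here. The scaling therefore rests on controls, and an error in it would shift every gene of a sample together. The normalization between samples was kept as deposited.

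Of 10928 probe sets, 7245 have a gene in the platform annotation, 1 of them with several genes. Through a RefSeq gene table of the R64 assembly, used for names and gene order without its coordinates, 5498 probe sets matched a gene of Saccharomyces cerevisiae. They represent 5449 genes, of which 47 have several probe sets. The brightest probe set without a suffix letter was taken for each gene, and 81 genes were read by a probe set whose suffix marks possible cross-hybridization. Of the genes, 499 have no name apart from their locus tag. The other 1746 named probe sets belong to genes outside this species and served as background. A further 3517 probe sets are unnamed here, and 166 are control probe sets. The background limit of a sample was the 95th percentile of the probe sets outside the species, 49.1 for wild type and 46.3 for acs2-Ts1, a choice made after seeing the data. Where the dimmer value of a named gene lay under that limit, or was no brighter than the deleted genes, only the values are given, without a fold. The silent gene STE3, at 214 in wild type, was not part of this rule.

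For each gene the log2 ratio of acs2-Ts1 over wild type was computed without a pseudocount. With 1 sample per group, no test, standard error or p-value could be had. The number of arrays limits the precision, and the values of single arrays were not analysed here. Intervals over genes are exact binomial 95% intervals for shares and order-statistic 95% intervals for medians, and they describe the set of genes on these arrays. The groups, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 10 highest and the 10 lowest log2 ratios among genes whose higher value reaches the median of that sample, up to 3 members at each end of a gene list under the same level rule, ACS2, ACS1, ACC1, the histone genes, and genes deleted or silent in these strains. Each of 33 gene lists was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn from the same 20 bins of mean log2 level. The bins include the members of the list itself. Lists under percentile 1 or over percentile 99 were said to stand apart, and chance alone would give 0.33 of 33 lists at each end. The percentile describes these samples and is not a test between strains. On simulated lists over the same 5449 genes, 1 of 96 lists without a shift lay over percentile 99 and 3 lay under percentile 1, while 93.8% of lists shifted by 1.0 on the log2 scale lay over percentile 99. The simulation permuted ratios within the same level bins, which makes genes independent, so its rate without a shift was largely fixed in advance. Genes of real lists may vary together, which the chance numbers do not allow for. Smaller shifts and downward shifts were not simulated. Genes near chromosome ends were planned by distance, but no chromosome lengths were given, so the 10 outermost protein-coding genes of each end were used.

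The alternatives were centring on bright control probe sets or on the all-gene median, filters at the 25th percentile and the median level, the mean of all probe sets of a gene, leaving out suffix probe sets, adding 32 to both values, fold thresholds of 1.5 and 3, random lists without level matching, and removal of the trend with level by a lowess curve of span 0.30. Added after seeing the data were a background filter, subtraction of background, centring on hybridization controls, and leaving out genes named by locus tag. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.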

Results

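Transcript levels were compared between yeast with wild-type ACS2 and yeast with the temperature-sensitive allele acs2-Ts1 after 60 min at 37 °C in rich medium. ACS2 encodes the acetyl-CoA synthetase of the cytosol and nucleus, which makes acetyl-CoA from acetate and supplies it for histone acetylation and lipid synthesis. The data are 2 deposited samples, 1 per strain, each the authors' mean of 2 arrays, with intensities for 5449 genes. There are no replicates, so every difference below is between these samples, and "higher" and "lower" describe acs2-Ts1 relative to wild type. As a yardstick within the arrays, 27 bacterial and phage hybridization controls had a median log2 ratio of -0.005 and an SD of 0.17, and probe sets of the same gene differed by a median SD of 0.20 and a pooled SD of 0.39 over 34 genes. The hybridization controls may be those the authors fitted on, which would by itself keep their ratios small. Probe sets outside the species, near background, had a median of -0.32 and an SD of 0.36.

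The ACS2 transcript was present in both strains at a similar level, 10257 in wild type and 12426 in acs2-Ts1, a log2 ratio of 0.28, and both values lie in the bright range where ratios were closest to 0. As both strains carry the gene on a plasmid, its level does not check the sample labels. ACS1, which encodes the other acetyl-CoA synthetase of yeast, read 623 and 784. ACC1, the acetyl-CoA carboxylase of fatty acid synthesis, was 1.52-fold lower, at 5129 and 3375.

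The main question was how transcript levels across the genome differ when the ACS2 enzyme is impaired. The data hold no measure of enzyme activity and no sample at a lower temperature, and the plasmids of the strains have different names. A difference from strain, plasmid or culture that exists at any temperature therefore cannot be told apart from an effect of the impaired enzyme. Most transcripts were lower in acs2-Ts1. Of 5449 genes, 4707 were lower (86.4%, exact binomial 95% interval 85.4 to 87.3 over genes) and 742 were higher. The median log2 ratio was -1.12 (95% interval over genes -1.15 to -1.10), a 2.18-fold lower level, and the median intensity was 586 in wild type and 259 in acs2-Ts1. At least 2-fold lower were 3048 genes (55.9%), and at least 2-fold higher were 200 (3.67%). At the 4-fold threshold these counts were 518 and 45. The summed intensity of all genes in acs2-Ts1 was 74.9% of that in wild type. These directions rest on the authors' scaling to controls. Centred on the all-gene median, which assumes no global shift, 49.99% of genes were lower, 360 were at least 2-fold lower and 896 at least 2-fold higher. Medians of gene groups are therefore given below both as measured and relative to the all-gene median.

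The difference was smaller for abundant transcripts. In the 545 genes with the highest mean level the median log2 ratio was -0.18, against -1.47 in the bin from 88.7 to 154 and -1.14 in the bin from 532 to 789. Binned by wild-type level instead, the median stayed between -1.32 and -1.31 from 136 to 771 and was -0.36 in the top bin. That bin begins at 3420.2, while the highest signals were 19111 for TDH3 in wild type and 17223 for PGK1 in acs2-Ts1. The lowest bins lay near background, where probe sets outside the species also had a negative median log2 ratio, of -0.32. Of the 3048 genes that were at least 2-fold lower, 264 were below the background limit in acs2-Ts1.

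**Figure D1:**
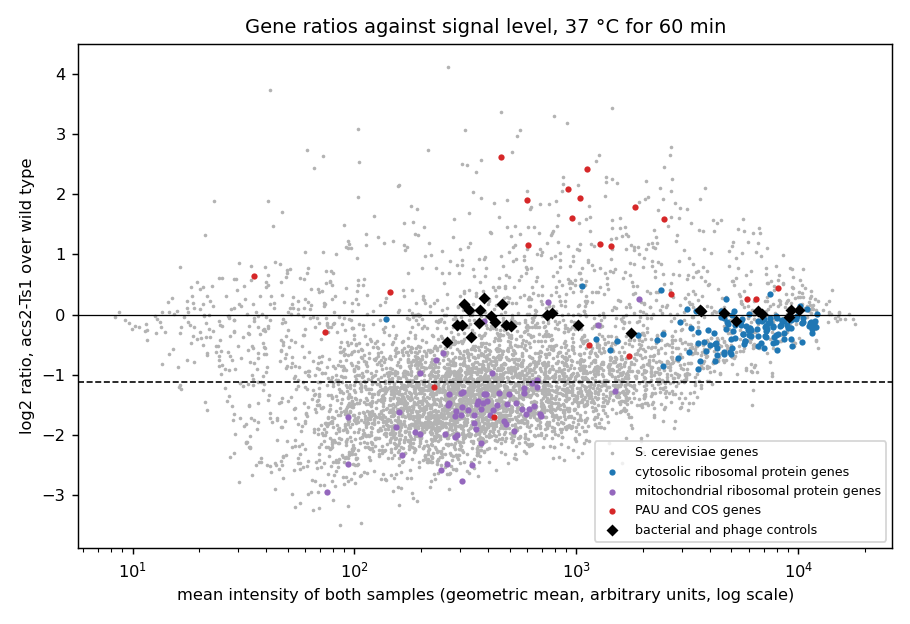
Each grey point is 1 gene, with the geometric mean of its intensities in both samples on the log-scaled x axis and its log2 ratio of acs2-Ts1 over wild type on the y axis. The dashed line marks the all-gene median of -1.12, the hybridization controls (black diamonds) lie around 0, and the cytosolic ribosomal protein genes lie at the bright end with a median of -0.24, which is 0.89 above the all-gene median.

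Among genes that met the level rule for naming, FUN14 had the lowest ratio, with 731 in wild type and 97.7 in acs2-Ts1 (7.48-fold lower). TSR2 and TSR4, which act in maturation of the small ribosomal subunit, were 7.26-fold and 6.18-fold lower. MRPS8, a mitochondrial ribosomal protein gene, was 6.81-fold lower, and TIM9, for import into the mitochondrial inner membrane, was 6.28-fold lower. LRO1, an acyltransferase of triacylglycerol synthesis, was 6.24-fold lower. The other members of the lowest 10 were MPM1 (6.63-fold lower), POF1 (6.45-fold), GPM2 (6.31-fold) and OTU1, which read 818 in wild type and 132 in acs2-Ts1.

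The highest ratio under the same rule was that of PUT4, the proline permease gene, with 63.4 in wild type and 1100.5 in acs2-Ts1. No fold is given, because its wild-type value was no brighter than that of the deleted gene LEU2, at 68.0. SER3, for the entry step of serine synthesis, was 10.8-fold higher at 442 and 4780. ARG3, for ornithine carbamoyltransferase of arginine synthesis, was 6.90-fold higher at 1016 and 7014. CMC4, for a protein of the mitochondrial intermembrane space, was 9.88-fold higher, and RSB1, involved in export of sphingoid bases, was 8.37-fold higher. The remaining 5 genes have no name apart from their locus tag. Of these, YER188C-A was 10.3-fold, YGL007C-A 9.10-fold, YCL042W 8.38-fold and YOR394C-A 7.85-fold higher, while YBL071C-B read 302 in acs2-Ts1 and 35.7, below background, in wild type. In wild type RSB1, YER188C-A, YCL042W and YOR394C-A were dimmer than the silent gene STE3, at 214, so their folds may be differences against background. Genes known only by locus tag were at least 2-fold higher in 41 of 499 cases (8.22%), and named genes in 159 of 4950 (3.21%).

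**Figure D2:**
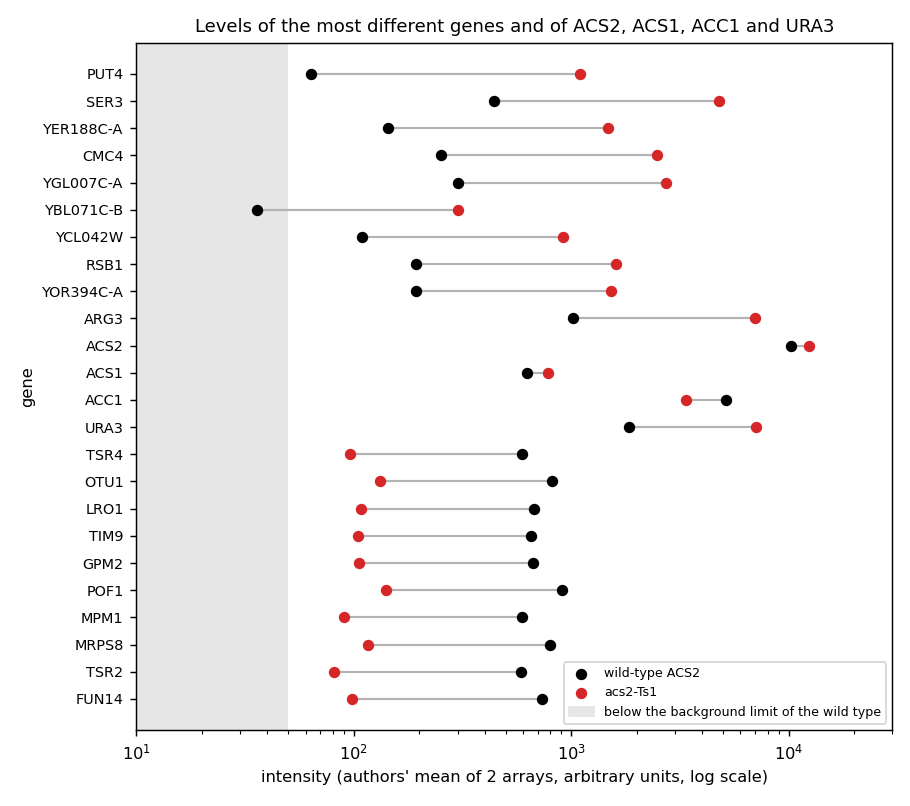
Intensity of the 10 genes with the highest and the 10 with the lowest log2 ratio, and of ACS2, ACS1, ACC1 and URA3, in wild type (black) and acs2-Ts1 (red), on a log-scaled axis in arbitrary units. PUT4 lies furthest apart, at 63.4 and 1100.5, whereas ACS2 lies at 10257 and 12426.

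Genes for making proteins were mostly lower as measured, to very different degrees. Of 66 measured mitochondrial ribosomal protein genes, 58 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -1.57 (-0.44 relative to the all-gene median, percentile 0.10 among level-matched lists). MRPL20 and MRPL44 were 6.01-fold and 5.69-fold lower, while RSM10 read 695 and 805. The list was drawn by a pattern of gene names, so a member such as MRP8, at 1744 and 2095, may not encode a ribosomal protein. Restricted to genes at or above the median level, this list no longer stood apart, although its median moved further from that of all genes, to -0.56. Of 76 ribosome biogenesis genes, 59 were at least 2-fold lower (median -1.29, -0.16 relative to all genes, percentile 6.32), among them UTP14 (4.58-fold), DBP3 (3.97-fold) and ENP1 (3.96-fold). Subunits of RNA polymerases I and III were at least 2-fold lower in 15 of 20 cases (median -1.35, -0.23 relative to all genes), with RPA43 5.05-fold lower. By contrast, 0 of 127 cytosolic ribosomal protein genes differed by 2-fold. Their median was -0.24, a direction that turns to 0.89 relative to all genes and to -0.08 with the trend with level removed. Their percentile was 3.84, slightly low among random lists of the same level. Those lists were drawn from bins that include these 127 genes, so the comparison is not with other bright genes alone. The 18 cytosolic aminoacyl-tRNA synthetase genes were all lower, 8 of them at least 2-fold, including HTS1 (3.11-fold) and VAS1 (2.84-fold). Their median of -0.97 lay 0.15 above the all-gene median but at percentile 0.49 of lists of the same level, where the median of random lists was -0.57, and without level matching the list did not stand apart. Among 10 subunit genes of RNA polymerase II, RPB5 alone was at least 2-fold lower (list median -0.82, 0.30 relative to all genes).

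Stress genes divided by class. Of 27 heat shock and chaperone genes, 7 were at least 2-fold lower, led by HSP30 (5.55-fold), SSE2 (4.55-fold) and STI1 (2.85-fold), and only SSA3 was at least 2-fold higher (2.33-fold). HSP12 and HSP26 read 10297 and 10924 in wild type and 12755 and 13057 in acs2-Ts1. The median of the list was -0.53, which is 0.60 above the all-gene median yet at percentile 0.030 among lists of the same level. Without level matching it lay over percentile 99. The 30 genes of general stress and reserve carbohydrate comprised 21 higher and 9 lower genes, with 3 at least 2-fold higher and 3 at least 2-fold lower. Their median of 0.28 (1.41 relative to all genes, and 0.93 with the trend with level removed) lay above all 10000 level-matched lists. GAC1, a regulator of glycogen synthesis, was 5.64-fold higher, and XBP1 and DDR2 were 2.28-fold and 2.04-fold higher, while TPS3, GRE3 and UGA2 were 3.05-fold, 2.91-fold and 2.86-fold lower. Oxidative stress genes had a median of -0.22 (0.91 relative to all genes, percentile 98.7), with 4 of 22 at least 2-fold lower, including GRX2 (2.78-fold) and GLR1 (2.60-fold). The list lay over percentile 99 with the background filter (99.02), without genes named by locus tag (99.06) and without level matching. It fell to percentile 90.3 with the filter at the 25th percentile of level and to 84.4 with that at the median. As the background filter chooses genes by the higher value, it is not taken as support. Omitting genes named by locus tag left the list median unchanged and removed comparison genes with a higher median, so it is not taken as support either.

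Carbon metabolism was mixed. In the acetyl-CoA and acetate list of 17 genes, YAT1, a carnitine acetyltransferase, was 2.78-fold higher, and 4 genes were at least 2-fold lower, among them PDX1 (3.81-fold) and LAT1 (3.01-fold) of the pyruvate dehydrogenase complex. In the glyoxylate and gluconeogenesis list of 13 genes, 3 were at least 2-fold higher, namely the regulator SIP4 (6.64-fold), isocitrate lyase ICL1 (2.88-fold) and peroxisomal citrate synthase CIT2 (2.57-fold), and 3 were at least 2-fold lower, including MDH3 (3.35-fold). The medians of these lists were -0.10 and -0.14, which become 1.02 and 0.98 relative to all genes, both at percentile 99.8. With genes under the 25th percentile of level left out, neither list stood apart, although their medians relative to all genes were still 0.84 and 0.99. With the filter at the median level the acetyl-CoA list did not stand apart (percentile 94.3), while the glyoxylate list, with 6 genes left, did (99.4). That filter chooses genes by the higher value, which can favour higher genes, so the position of the glyoxylate list under it is not taken as support. Glycolysis and fermentation genes, among the brightest on the arrays, were within 2-fold in 16 of 16 cases (median -0.04, 1.09 relative to all genes and -0.15 with the trend with level removed). The 14 hexose transporters had a median of 0.01 (1.13 relative to all genes, percentile 99.3), with HXT2 2.31-fold higher and HXT1 2.90-fold lower. Of 15 genes of the tricarboxylic acid cycle, 7 were at least 2-fold lower (median -0.90, 0.22 relative to all genes), including FUM1 (3.16-fold), while IDH1 read 4311 and 6048. Of 32 respiratory chain and ATP synthase genes, 7 were at least 2-fold lower, and QCR6 and COR1 of the cytochrome bc complex were 3.05-fold and 2.27-fold higher (median -0.73, 0.39 relative to all genes).

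Lipid genes were mostly lower as measured. Of 16 genes of fatty acid synthesis and elongation, 7 were at least 2-fold lower, including PHS1 (3.69-fold) and FAA3 (3.58-fold), while FAS1 was 1.69-fold higher at 7222 and 12185 (list median -0.78, 0.34 relative to all genes). Of 18 phospholipid genes, 9 were at least 2-fold lower, with CKI1 4.72-fold and EPT1 4.14-fold lower, and INO1, for inositol synthesis, was 2.18-fold higher (list median -0.98, 0.15 relative to all genes). Ergosterol synthesis had 4 of 24 genes at least 2-fold lower, led by ERG12 (3.67-fold), and a median of -0.39, close to the -0.34 of random lists of the same level (0.73 relative to all genes, and 0.15 with the trend with level removed).

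Histone transcripts were near the wild-type level as measured, at 0 of 9 genes with a 2-fold difference. The log2 ratios were 0.00 for HTA1, 0.35 for HTA2, -0.24 for HTB1, 0.13 for HTB2, 0.39 for HHT1, 0.56 for HHT2 and 0.29 for HHF1, the latter from a probe set that may cross-hybridize. The variant HTZ1 and the linker histone HHO1 had -0.22 and -0.78, and HHF2 was not analysed here. The list median of 0.13 was 1.26 relative to all genes, and 0.62 with the trend with level removed, and lay at percentile 96.9. Genes of the histone acetyltransferase complexes SAGA and NuA4 were at least 2-fold lower in 12 of 24 cases, including TRA1 (2.73-fold), while EPL1 was 2.24-fold higher (list median -1.07, 0.06 relative to all genes). Histone deacetylase genes were at least 2-fold lower in 10 of 18 cases, including RPD3 (2.51-fold), with a median of -1.11 (0.02 relative to all genes).

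Of 51 amino acid biosynthesis genes, 23 were at least 2-fold lower, including LYS12 (4.29-fold) and SER2 (3.63-fold), and 5 were at least 2-fold higher. These were SER3 and, all in arginine synthesis, ARG3, ARG1 (2.99-fold), CPA1 and ARG8, the latter pair named after their log2 ratios of 1.44 and 1.09 were seen. The list median was -0.93, which is 0.19 above the all-gene median but at percentile 0.86 of lists of the same level, a position lost with genes under the 25th percentile of level left out, where the difference from all genes stayed similar at 0.18, with the filter at the median level, without genes named by locus tag and without level matching. The 24 sulfur and methionine genes were divided, with 12 higher and 12 lower, and had a median of 0.01 (1.13 relative to all genes), above all 10000 level-matched lists. STR3 was 5.17-fold higher, MET28 read 74.6 and 329.7, and CYS4 was 2.76-fold lower. Of 13 phosphate starvation genes, 8 were at least 2-fold lower, including PHO81 (4.13-fold), and the phosphate transporter PHO89 was 5.88-fold higher (list median -1.05, 0.07 relative to all genes).

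The 30 cell wall genes had a median of 0.18 (1.30 relative to all genes, and 0.28 with the trend with level removed). Their percentile was 99.98, with a random-list median of -0.24, and 6 were at least 2-fold higher, including PIR3 (4.56-fold), DAN1 (4.45-fold) and TIR4 (4.17-fold), and 3 were at least 2-fold lower, including FIT2 (3.22-fold). The 22 seripauperin (PAU) and COS genes had a median of 0.89 (2.01 relative to all genes), above all 10000 level-matched lists, and 11 were at least 2-fold higher, including PAU3 (6.17-fold) and PAU2 (5.37-fold). In this list 13 of 22 genes were read by probe sets that may cross-hybridize among near-identical copies. Without them the list did not stand apart, and the other 9 genes had a median of -0.29 (0.85 relative to all genes). That value is the ratio of COS111, which a pattern of gene names brought in and which may not belong to the family. The genes left out were 10 of 13 PAU genes but 3 of 9 COS genes. Leaving them out therefore also changes the mix of the families, so it does not show an effect of cross-hybridization. Over the 10 outermost genes of each chromosome end, 235 measured genes had a median of -0.61 (0.51 relative to all genes), above all 10000 random lists of the same level, with 21 at least 2-fold higher and 89 at least 2-fold lower. Leaving out PAU and COS genes and genes below background in either sample, 172 genes had a median of -0.79, against -1.17 for random lists of the same level.

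**Figure D3:**
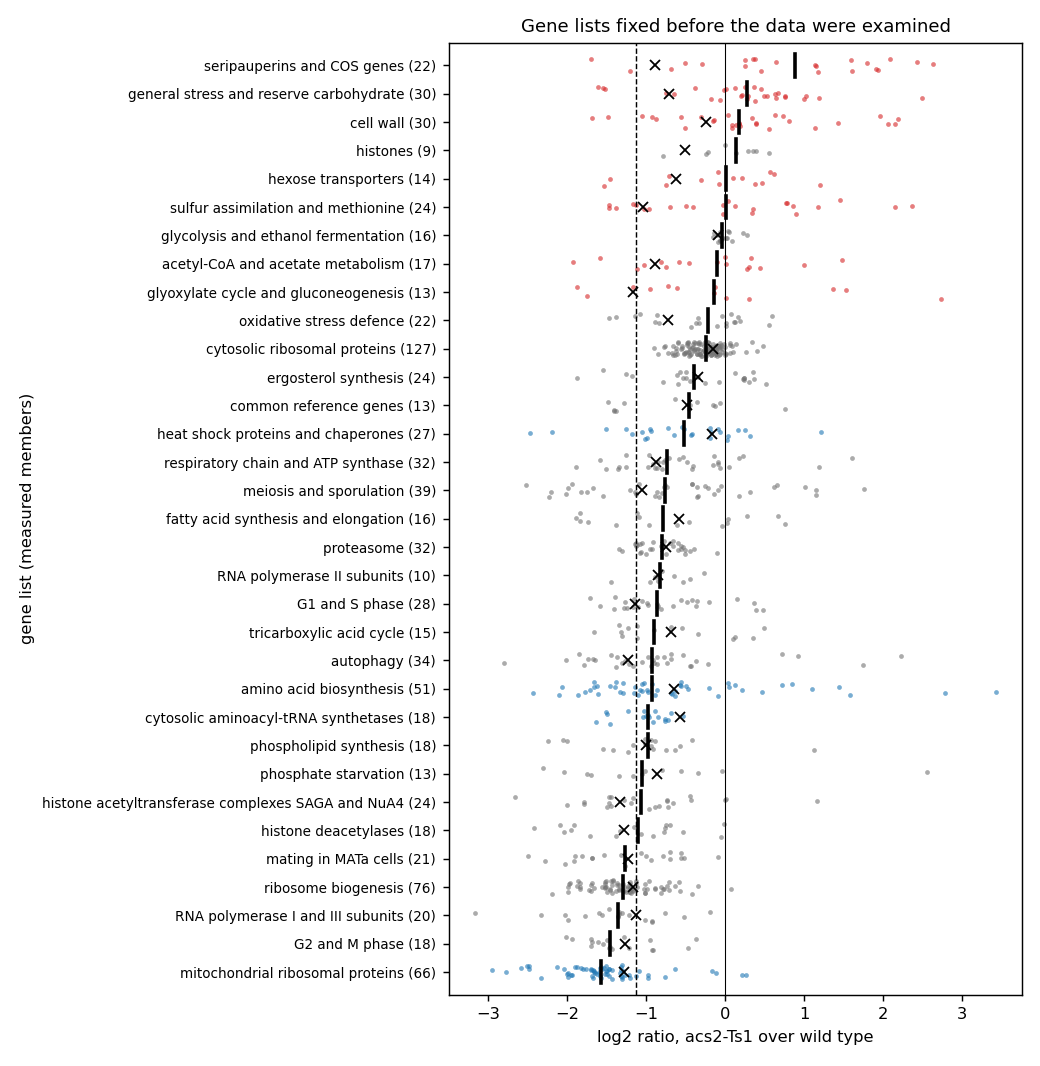
Log2 ratio of acs2-Ts1 over wild type (x axis) for each measured member (points) of 33 gene lists (y axis), with list medians (black bars) and the median of level-matched random lists (crosses). The dashed line is the all-gene median of -1.12, and colour marks the 7 lists over percentile 99 (red) and the 4 lists under percentile 1 (blue).

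Deleted and silent genes were read to look at background. LEU2 and MET17, deleted in both, read 68.0 and 47.9 in wild type and 77.5 and 77.5 in acs2-Ts1. The wild-type values of PUT4 (63.4) and MET28 (74.6) were no brighter than the highest of these readings, so no folds are given. The alpha-specific genes, silent in cells of mating type a, read 25.5 and 21.0 for MF(ALPHA)1, 64.5 and 61.8 for MF(ALPHA)2, and 214 and 59.0 for STE3. STE3, MF(ALPHA)2 and LEU2 lay above the background limit in both samples, and MET17 did in acs2-Ts1. Passing this limit therefore does not show that a transcript is present. As STE3 read 214 in wild type, folds of higher genes with a dimmer wild-type value may be differences against background. Among these are SIP4, ICL1, IME2, GAC1, STR3 and PAU3, with wild-type values from 83.5 to 184. HIS3, whose deletion may leave part of the gene, read 1650.1 and 882. Among 13 common reference genes, ACT1 read 14269 and 13059.9 and PGK1 18028 and 17223, while UBC6 and ALG9 were 2.66-fold and 2.65-fold lower and CDC34 was 1.69-fold higher (list median -0.45, 0.67 relative to all genes). URA3, the marker of the ACS2 plasmids, which have different names in the strains, was 3.81-fold higher, at 1853 and 7059.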

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

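All tests in this part, which are thresholds on values, were chosen after the result was seen. Signals outside the gene comparison were looked at because they were not used there. Among 16 control probe sets for the larger ribosomal RNAs of the species, 13 were above background in both samples. Of these, 10 were higher in acs2-Ts1, and the 13 had a median of 1.43-fold and log2 ratios from -0.46 to 1.14. Among 3517 unnamed probe sets, 472 were above background in at least 1 sample. Of these, 25 were at least 2-fold higher and 112 at least 2-fold lower in acs2-Ts1. Some of the 25 lay below the limit in wild type, for example at 19.1 and 48.2, so their difference is one against background.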

How the results depend on the processing

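The background filter, the background subtraction, the centring on hybridization controls and the omission of genes named by locus tag were chosen after the data were seen. Centred on the all-gene median, the median log2 ratio was 0.0000, 49.99% of genes were lower, 360 genes were at least 2-fold lower and 896 at least 2-fold higher, and ACS2 had a log2 ratio of 1.40, all by construction of that centring. Centring on 47 bright control probe sets raised every log2 ratio by 0.02, to an all-gene median of -1.10. Some of them may be controls the authors fitted on, so this small shift does not check the scaling. With genes under the 25th percentile of level left out, 85.0% were lower. With those under the median level left out, the median was -0.96, 80.1% were lower, 1392 were at least 2-fold lower, and 2 lists stood apart below. Adding 32 gave a median of -0.999, subtracting background gave -1.18 with 84.8% lower, and omitting genes named by locus tag gave -1.15 with 87.9% lower. A 1.5-fold threshold gave 329 higher genes, and a 3-fold threshold gave 1408 lower and 86 higher. Against random lists without level matching, 13 lists stood apart above and 1 below. Of 297 medians of gene lists relative to all genes over the 9 settings that alter them, 271 stayed within the interval of the reported value, 22 moved outside it and 4, of lists that stand apart, reversed. The latter were aminoacyl-tRNA synthetases at -0.014 with only genes at or above the median level, and, with the trend with level removed, aminoacyl-tRNA synthetases at -0.44, heat shock genes at -0.36 and amino acid biosynthesis at -0.24. That removal also brought respiratory chain genes to 0.17 and mitochondrial ribosomal proteins to -0.27. Of the lists that do not stand apart, 11 changed sign relative to all genes under some setting, in 16 values. With the trend with level removed these were cytosolic ribosomal proteins (-0.08), glycolysis (-0.15), fatty acid synthesis (-0.23), reference genes (-0.22), proteasome (-0.09), phosphate starvation (-0.25), the tricarboxylic acid cycle (-0.03) and phospholipid synthesis (-0.0033). The other such lists were SAGA and NuA4 (-0.12) and histone deacetylases (-0.22) with the filter at the 25th percentile, and mating genes (0.018) with 32 added. Apart from the fewer genes left by filters, the cause was not tested. Signal over background limits the dim genes, as 5258 genes were above the limit in wild type and 5006 in acs2-Ts1. Some deleted or silent genes passed this limit too, so these counts do not give the number of expressed genes. No paired analysis was possible because each group has 1 sample.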

Other observations

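The groups of DAN and TIR, PAU, COS, nitrogen and origin licensing genes were chosen after the values were seen, and so were the tests on the lower signal of most genes, on transcript level and on URA3, while the other gene lists were planned. Anaerobically expressed cell wall genes were higher together. Of 6 DAN and TIR genes, 5 were at least 2-fold higher in acs2-Ts1, with a median of 3.24-fold, for example TIR3 at 1069 and 4147 and DAN4 at 952 and 2572, and none of them was read by a probe set with a suffix. All but DAN4 also belong to the planned cell wall list, so the high positions of both rest partly on the same genes. The PAU and COS genes likewise form a planned list given above. Among 13 PAU genes, 10 were at least 2-fold higher with a median of 3.05-fold, although 10 of the 13 were read by probe sets that may cross-hybridize, and 9 COS genes had a median log2 ratio of 0.25 (1.38 relative to all genes). Genes for the use of poor nitrogen sources diverged. GAP1, the general amino acid permease, was 6.30-fold higher, the ammonium permease MEP2 3.09-fold and the proline oxidase PUT1 3.01-fold, beside PUT4, whereas GDH2 was 2.23-fold lower and the allantoin gene DAL1 read 268 and 41.7. Over 19 such genes the median log2 ratio was -0.47, a direction that turns to 0.65 relative to all genes (percentile 99.4, with a random-list median of -1.13), with 4 at least 2-fold higher and 4 at least 2-fold lower.

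Several cell cycle and differentiation groups from the planned lists were mostly lower as measured. Of 18 genes of G2 and M phase, 13 were at least 2-fold lower, including ALK1 (4.04-fold) and CHS2 (3.83-fold), with a median log2 ratio of -1.46 (-0.34 relative to all genes). Of 28 genes of G1 and S phase, 11 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.86 (0.26 relative to all genes). CDC45 and RFA3 were 2.65-fold and 2.63-fold lower, and the G1 cyclins CLN1 and CLN2 read 713 and 1817 in wild type and 922 and 2380 in acs2-Ts1. Among 14 origin licensing genes, 12 were at least 2-fold lower (median -1.55, -0.42 relative to all genes), at percentile 9.43 with a random-list median of -1.28. MCM6 read 560.3 and 65.4 and ORC1 291 and 25.7, and as both acs2-Ts1 values lie under the 77.5 of the deleted gene LEU2, no fold is given. Of 21 mating genes, 13 were at least 2-fold lower, including STE6 (4.08-fold) and STE12 (3.75-fold), with a median of -1.27 (-0.14 relative to all genes). Of 39 meiosis and sporulation genes, 14 were at least 2-fold lower and 4 at least 2-fold higher, including the kinase gene IME2 (3.37-fold), with a median of -0.76 (0.36 relative to all genes, percentile 91.1). This list stood apart above with background subtracted (percentile 99.1) or without genes named by locus tag (99.7). Subtraction sets values to at least 10, which can bring ratios of dim genes towards 0, and the list median became -0.36. Omitting genes named by locus tag left the list median at -0.76. It only removed comparison genes with a higher median log2 ratio, of -0.63 against -1.15 for the other genes. The list also stood apart with the filters at the 25th percentile and on background. These choose genes by the higher value, which can favour higher genes. None of these settings is taken as support. Of 34 autophagy genes, 15 were at least 2-fold lower, while ATG40 and ATG41 were 4.66-fold and 3.36-fold higher (list median -0.93, 0.20 relative to all genes, percentile 96.9). The autophagy list stood apart above with the trend with level removed (99.2) or without genes named by locus tag (99.1). That omission changed only the comparison genes, so it is not taken as support. All 32 proteasome genes were lower, 10 of them at least 2-fold, including PUP2 (2.54-fold), with a median of -0.79 (0.33 relative to all genes and -0.09 with the trend with level removed).

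The labels say that expression shifted globally. The lower signal of most genes may come from less RNA per cell or from less labelled RNA on the arrays. A single factor for all genes is not the whole difference between the samples, as 11 of 33 gene lists stood apart from lists of the same level. Chance gives 0.66 if genes are independent. A common factor cancels in that comparison, so it does not show whether such a factor lowered the signal of most genes. A smaller amount of labelled RNA beside differences of single genes stays open, since the 545 brightest genes of wild type had a median log2 ratio of -0.36 in place of -1.12, but the brightest of their signals may be saturated. The Bacillus poly-A and tryptophan controls could track the amount of RNA if their transcripts were added. They read a median of 17.8 and 13.7, below the 21.0 and 16.9 of probe sets outside the species, so they cannot show it. RNA degradation stays open too, as the 3' to 5' ratio of 9 sets of control probe sets, where ACT1 and SPT15 have more than 1 set each, shifted by a median of 0.12 on the log2 scale with an SD of 0.52.

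The smaller difference of abundant transcripts could be biological, for example through stable transcripts, which was not tested, or could come from saturation of bright probe sets. Across 3202 genes with both values between 100 and 2000, Spearman's rho of log2 ratio with mean level was 0.195, across genes that are not independent replicates, and the limits of that range themselves lower rho, so it does not decide. Of the 545 genes brightest in wild type, 85 were at least 2-fold lower, so bright probe sets could still show a difference. A normalization curve that varies with level cannot be told apart from either. Bright hybridization controls exceeded dim ones by a log2 ratio of 0.089, but these may be the controls the authors fitted on. Even the dim ones read at least 292 in wild type and 224 in acs2-Ts1, so they do not cover dim genes. Near background, probe sets outside the species had a median log2 ratio of -0.32.

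URA3 was 3.81-fold higher, and 3 further control probe sets for it read 599, 773 and 2149 in wild type and 2640, 3492 and 6361 in acs2-Ts1. A candidate explanation is a larger number of plasmids per cell in acs2-Ts1. ACS2 on the same plasmid had a log2 ratio smaller by 1.65, but an equal ratio would have needed a signal of 39083, above the highest signal of 17223, so this stays open. Induction of the whole pyrimidine pathway is argued against by 8 other genes of pyrimidine synthesis. Of these, 0 were at least 2-fold higher and 5 at least 2-fold lower, with a median log2 ratio of -1.16 (-0.04 relative to all genes). URA1, URA4 and URA10 had a median of -1.43, below the all-gene median of -1.12, while URA2 (-0.39) and URA5 (-0.29) lay above it. The plasmids of the strains have different names, and a difference between their URA3 markers was not tested.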
